A study of Mus musculus with 2 samples.

How the data were processed

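The series compared RNA from mouse brain (strain C57BL/6, wild type, tissue given as whole brain) before and after enrichment of synaptosomes, the pinched-off nerve endings with attached postsynaptic membrane that form when brain tissue is homogenised. Per the labels' protocols, brains were homogenised in sucrose buffer, nuclei were spun down at low speed, and the supernatant was run on a Percoll density gradient. The layer between 3% and 10% Percoll was collected as the synaptosome fraction. There were 2 libraries, 1 from total homogenate and 1 from the synaptosome fraction. Libraries were made with a stranded mRNA kit and sequenced as 100-base reads, per the labels, which name both paired and single reads without saying which applied to these 2 libraries.

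The authors deposited, for each library, expected counts, TPM and FPKM for each of 30383 transcripts. They also deposited a table of both libraries with 1 signal value per gene. Per the submitters' processing notes the tools were FastQC, TopHat 1.3.3, RSEM 1.2.5 and edgeR 3.0.6, and the build was mm10. The role and settings of each tool are not given in the sources used here. The deposited expected counts were estimates that can be fractional: 61.4% of the transcript values in the homogenate and 67.88% in the synaptosome fraction were whole. TPM, as deposited by the authors, is scaled to the same sum in each library, which removes the depth. FPKM, as deposited by the authors, was proportional to TPM within each library and was not used. The deposited signal was the gene's summed expected count times a factor of 0.7983 in the homogenate and 1.2527 in the synaptosome fraction, within 0.5% for 97.06% and 97.26% of genes. How the authors chose that factor is not given in the sources used here. The files held 0 rows on the mitochondrial chromosome, so a planned list of 13 mitochondrially encoded mRNAs, their share of the counts and the marker mt-Co1 were not analysed here. Values of genes with near-identical copies are uncertain, since such estimates may divide reads among similar transcripts, which was not tested here.

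For the present work, expected counts were summed over the transcripts of each gene symbol (23329 genes) and rounded to whole numbers. Totals were 15210857 for the homogenate and 13709539 for the synaptosome fraction. Scaling used TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.1863 for the homogenate and 0.8429 for the synaptosome fraction. TMM assumes that most genes do not differ, so every ratio is relative to the typical gene of the same library. Genes with a mean of at least 1 CPM (counts scaled to a common library size) over both libraries were kept, 14153 in all. Each gene's log2 ratio, synaptosome over homogenate, was given with an exact 95% Clopper-Pearson interval of the ratio given the summed count. Intervals cover counting error of the rounded estimates only, without the error of assigning reads to transcripts. PCR copies are not independent molecules, so even counting error may be understated. With 1 library per fraction there was no replicate, no spread between animals or preparations could be estimated, and no p-value is given. In place of a test, a rule of size was fixed: a gene was counted as higher or lower when its ratio was at least 2-fold and its interval excluded 0. A gene with 0 counts in a library was given a floor of 3 counts in that library and its fold is given against that floor, with the limit of the exact counting interval, which lies lower, beside it.

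Before the data were examined, 25 gene lists were fixed for synapses, other parts of the neuron, translation, energy metabolism, the nucleus and every other cell type of the brain, and 24 could be measured. For each list the median log2 ratio was set against 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list was taken to stand apart when it lay outside the middle 95% of the random lists, which describes these 2 libraries and no others. Lists overlapped: Camk2a, Shank1, Dlg4 and Arc, among others, were in more than 1. Genes named in the text were fixed by rule: the 12 highest and 12 lowest ratios among genes with a mean of at least 10 CPM, leaving out predicted genes, small RNAs, clone names and pseudogenes; in each list, examples from the 2 most abundant members and the members with the highest and lowest ratio; and 17 check genes, of which some results are not reported here. Other genes named were chosen after their values were seen. Map2 is listed in the files under its older symbol, Mtap2, Pantr1 as 2610017I09Rik and Pnisr as Sfrs18. Coordinates are those of the files, on mm10.

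Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated counts with the libraries' own means and totals, for the comparison of synaptosome with homogenate on 14088 genes. The interval held the true ratio for 95.69% of genes, and 23 of 13871 unchanged genes passed the rule of size. Of genes changed 3-fold 96.8% passed, of those changed 4-fold 100%, and of those changed 1.5-fold 2.94%. Of 100 random lists with no shift, 5 lay outside the middle 95%. The simulated counts varied by counting error alone around an average profile with few genes changed. These figures are therefore no error rates for the real libraries. Near-identical copies of the named genes were searched with BLAST 2.17.0 against a reference transcriptome, at 95% identity over at least 50% of the query. Hbb-b2 and Tgoln2 were not searched. Alternatives were scaling by library totals or by DESeq2 1.42.0 size factors, the authors' signal or TPM with a pseudocount of 1, other expression filters and thresholds, log CPM with a prior count of 2, means in place of medians, and random lists matched on transcript length. Alternatives added after the data were seen were matching on GC content, leaving out Rn45s and Gm20594, sums with near-identical copies, lists without shared members, and library totals for the lists and annotation terms added later. Lists matched on transcript length or GC content were matched on that trait in place of mean expression. Another 10 gene lists, 18 gene ontology annotation terms of the authors' table and markers of brain regions were also chosen after the first results.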

Results

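RNA from the synaptosome fraction of wild-type mouse brain was compared with RNA from total homogenate to find which mRNAs were enriched at synapses, the purpose named in the series title. There was 1 library of each kind, with 15210857 estimated counts for the homogenate and 13709539 for the synaptosome fraction. At least 1 count was found for 17456 genes in the homogenate and for 16763 in the synaptosome fraction. No value had a replicate, so each ratio compares these 2 libraries, and intervals cover counting error only.

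The synaptosome fraction held more mRNA of astrocytes, dendrites and cytosolic ribosomal proteins than the homogenate. It held less nuclear noncoding RNA and less mRNA of blood vessels and blood. Slc1a2, the main glutamate transporter of astrocytes, was 4.33-fold higher in the synaptosome fraction (95% counting interval 4.29 to 4.38), and Camk2a, a kinase whose mRNA is carried into dendrites, was 3.61-fold higher (3.56 to 3.65). Mbp, which encodes myelin basic protein and whose mRNA travels along oligodendrocyte processes, was 5.31-fold higher (5.26 to 5.36). Meg3, a long noncoding RNA held in the nucleus, was 4.52-fold lower (4.44 to 4.61), and Cldn5, a tight junction protein of brain endothelium, was 8.61-fold lower (5.47 to 14.3). Among abundant presynaptic mRNAs, Syp, a synaptic vesicle protein, was 2.74-fold higher, whereas Snap25, a membrane fusion protein, was 2.67-fold lower.

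Of 14153 genes, 1807 (12.8%) were at least 2-fold higher in the synaptosome fraction and 1288 (9.1%) were at least 2-fold lower, while 11058 lay between. The split depended on the scaling. With library totals in place of TMM, which moved every log2 ratio by -0.49 and put the median of all genes at -0.51 instead of -0.01, 636 genes were higher and 3629 lower, and with TPM 470 were higher and 3005 lower. All directions below are therefore relative to the typical gene. A log2 ratio above 0 by less than that shift lies below 0 under library totals. Ratios also tended to rise with abundance. Random lists matched on expression had medians of 0.64, 0.53 and 0.69 for the dendritic, synaptic vesicle and glycolysis lists. For the microglial and endothelial lists they had -0.04 and -0.05. An abundant gene given as higher can therefore lie below the usual ratio of equally abundant genes.

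**Figure D1:**
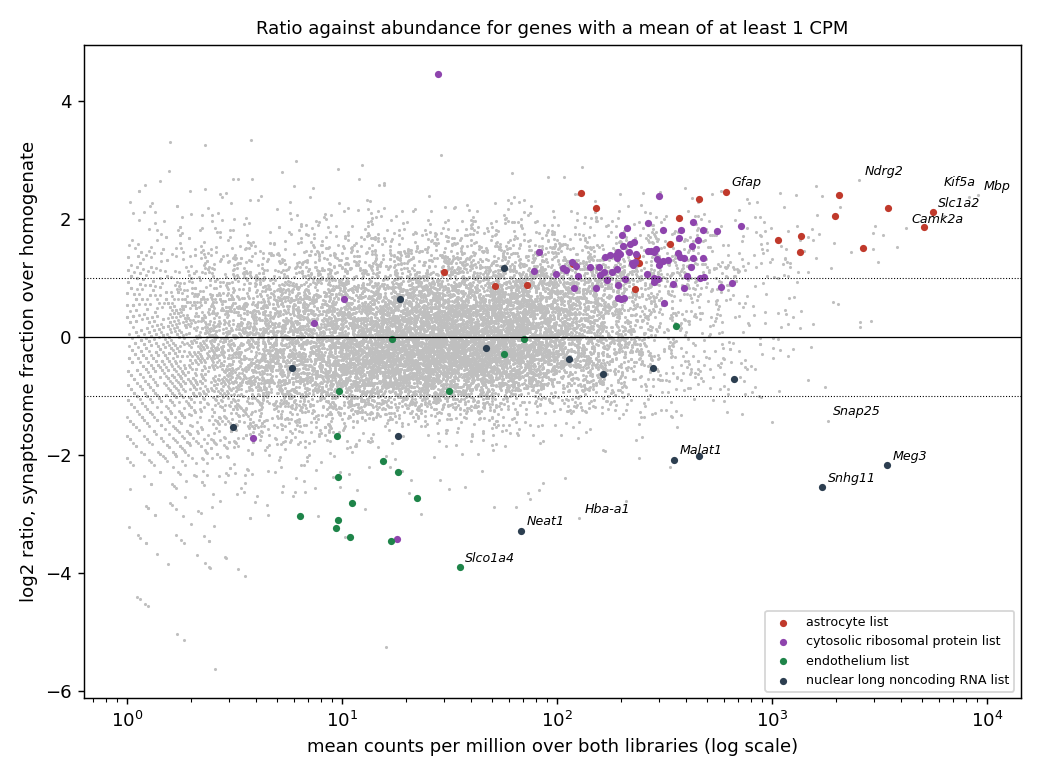
Log2 ratio of the synaptosome fraction over the homogenate (vertical axis) against mean CPM over both libraries (horizontal axis, log scale), 1 point per gene; colours mark 4 gene lists and dotted lines the 2-fold limits, and genes with 0 counts in a library are not drawn. Astrocyte genes and most ribosomal protein genes lie above 0, with medians of 1.68 and 1.27, and endothelial genes mostly below it, with a median of -2.33.

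Dendritic mRNAs were higher in the synaptosome fraction as a group. Of 24 measured members, 16 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 ratio of 1.28 that 14 of 10000 random lists reached. Kif5a, a kinesin heavy chain, was the highest member at 5.23-fold (5.18 to 5.28), and its share of all counts was 0.349% in the homogenate and 1.297% in the synaptosome fraction. Shank1, a postsynaptic scaffold, was 3.23-fold higher (3.11 to 3.36), and Arc, an activity-induced gene with dendritic mRNA, 2.29-fold higher (2.18 to 2.40). Dlg4, the scaffold PSD-95, was 1.88-fold higher (1.84 to 1.93). Map2, a dendritic microtubule protein, was 1.28-fold higher, with a log2 ratio of 0.35 that became -0.14 under library totals. Nrgn, a calmodulin-binding protein of spines, went the other way and was 1.45-fold lower (1.41 to 1.49). In the same pair of libraries the astrocyte list had a median of 1.68 and the endothelial list one of -2.33.

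Messages for the excitatory postsynapse followed the dendritic ones. Of 37 scaffold and glutamate receptor genes, 15 were at least 2-fold higher and 0 lower, with a median of 0.83 that 48 of 10000 random lists reached. Shank3 was 4.04-fold higher (3.87 to 4.22) and Grin1, the obligatory NMDA receptor subunit, 3.87-fold higher (3.76 to 3.97), while Baiap2 was 1.84-fold lower (1.72 to 1.97). Of 19 genes of the inhibitory postsynapse, 6 were at least 2-fold higher and 0 lower. Their median was 0.75, which 476 random lists reached, so the list did not stand apart. Gabrd, a subunit of extrasynaptic GABA receptors, was 2.85-fold higher (2.64 to 3.08), and Gphn, the inhibitory scaffold gephyrin, was 1.46-fold lower (1.33 to 1.61). Of 29 voltage-gated channel genes, 8 were higher and 0 lower, and their median of 0.62 was reached by 483 random lists. Among them Scn8a, a neuronal sodium channel, was 2.25-fold higher and Cacnb4, a calcium channel subunit, 1.56-fold lower. Astrocyte mRNAs (median 1.68) exceeded all 3 of these groups in the same library.

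Presynaptic mRNAs went in both directions. Of 44 synaptic vesicle and active zone genes, 11 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.29 that became -0.20 under library totals, and 1041 random lists lay as low. Against lists matched on transcript length or GC content in place of expression it lay near the high end (percentiles 97.14 and 94.76). Both lay within the middle 95%. As a mean, against lists matched on expression, the list lay at 0.16 and stood apart as low (percentile 0.4). Rims1, an active zone scaffold, was 3.44-fold higher (3.25 to 3.66) and Syt1, the calcium sensor of release, 1.47-fold higher. Snap25 was 2.67-fold lower (2.62 to 2.73), with 43688 counts in the homogenate and 10472 in the synaptosome fraction, and Syn1, a vesicle-tethering phosphoprotein, was 1.95-fold lower (1.89 to 2.02). Sncb was 2.56-fold lower and Rab3a, a vesicle GTPase, 2.39-fold lower. The astrocyte median in this library was 1.68.

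Neuropeptide and granin genes had 8 of 23 measured members at least 2-fold higher and 0 lower, with a median of 0.68 reached by 93 random lists. Vgf was 4.41-fold higher (4.23 to 4.60), and Scg2 and Chgb, proteins of dense-core vesicles, were 3.97-fold and 3.01-fold higher. Tac2, a tachykinin precursor, was 1.58-fold lower. The list no longer stood apart when only its 14 members with a mean of at least 10 CPM were used (median 0.41).

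**Figure D2:**
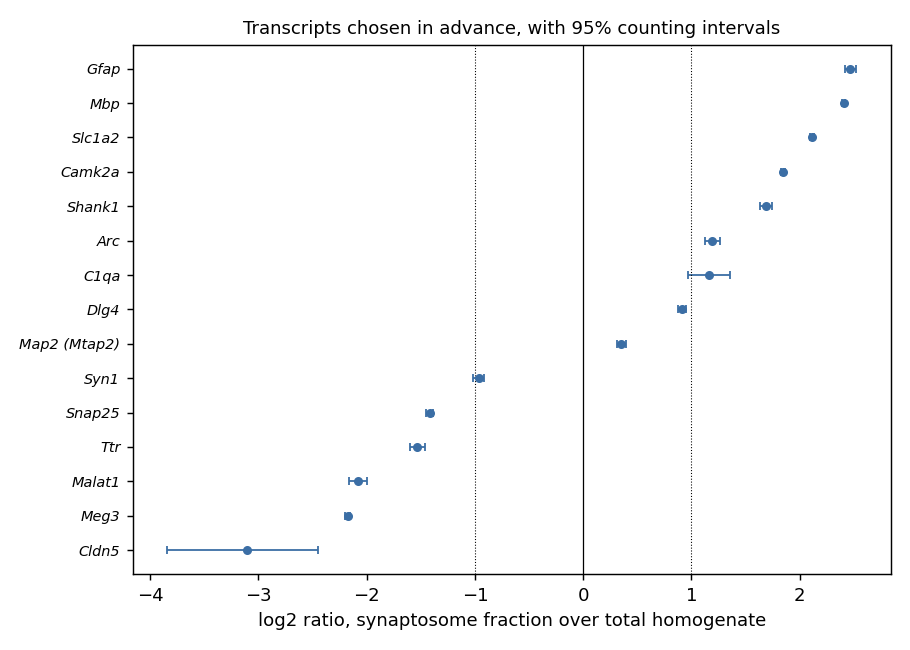
Log2 ratio of the synaptosome fraction over the homogenate (horizontal axis) for 15 transcripts chosen in advance (vertical axis), with 95% counting intervals as bars; dotted lines mark 2-fold. Gfap, at 2.47, lies highest and Cldn5, at -3.11, lowest; Map2 lies above 0 here and below it under library totals.

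Ribosomal protein mRNAs were higher almost throughout. Of 80 cytosolic ribosomal protein genes, 61 were at least 2-fold higher, with a median of 1.27 that none of 10000 random lists reached. Rpsa was 3.71-fold higher (3.60 to 3.82) and Rpl4 1.88-fold higher (1.83 to 1.94). The members at least 2-fold lower were Rps27 and Rpl26, and both have near-identical copies. Summed with those copies, a step chosen after the values were seen, the log2 ratio was 1.51 for Rps27 and 1.23 for Rpl26. Among ribosomal protein genes, only Rps27, Rpl26, Rpl34 and Rps14 were searched for copies. By annotation, a term chosen later, 149 ribosome genes had a median of 0.19, or -0.30 under library totals, and did not stand apart (percentile 85.62). Of those 149 genes, 45 (30.2%) were at least 2-fold higher and 2 (1.3%) lower, against 12.8% and 9.1% of all genes. Of 27 translation factor genes, 3 were at least 2-fold higher and 0 lower. These were Tpt1, the elongation factor Eef1a1 and Eef2, at 2.52-fold, 2.42-fold and 2.27-fold, while the initiation factor Eif2s1 was 1.94-fold lower (1.69 to 2.23). The median of translation factors was 0.17 and became -0.32 under library totals, and 1329 random lists lay as low.

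Genes of energy metabolism lay near the typical gene. Of 77 nuclear-encoded genes of oxidative phosphorylation, 8 were at least 2-fold higher and 0 lower, with a median of 0.33 that became -0.16 under library totals and that 1886 random lists reached. Cox4i1, a cytochrome oxidase subunit, was 2.52-fold higher (2.43 to 2.60) and Cox5a, another, 1.42-fold lower (1.33 to 1.52). Of 16 glycolysis genes, 1 was at least 2-fold higher, the astrocyte-enriched Aldoc at 5.33-fold (5.23 to 5.44). The glycolysis median was -0.00, which was low for genes so abundant, with 204 random lists as low. Matched on transcript length in place of expression, the list did not stand apart. Gapdh was 1.13-fold higher, with a log2 ratio of 0.17 that became -0.32 under library totals, and Eno2, the neuronal enolase, was 1.84-fold lower (1.78 to 1.90).

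Long noncoding RNAs of the nucleus were lower in the synaptosome fraction. Of 15 measured, 7 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.72 that 1 of 10000 random lists matched or passed. Meg3 made up 0.596% of all counts in the homogenate, more than any other gene, and 0.0936% in the synaptosome fraction. Neat1, the scaffold of paraspeckles, was 9.75-fold lower (8.15 to 11.8), Snhg11 was 5.83-fold lower (5.67 to 6.01), and Malat1, a nuclear speckle RNA, was 4.24-fold lower (4.00 to 4.49). The exception was Pantr1, at 2.25-fold higher (2.04 to 2.49). Of 25 mRNAs for nuclear proteins of neurons and chromatin, 3 were at least 2-fold lower and 1 higher, with a median of -0.32 that 75 random lists reached or passed. Neurod6, a transcription factor of cortical neurons, was 3.15-fold lower (2.75 to 3.62), and Zbtb20, read from 17 and 50 counts, was 4.59-fold higher (2.60 to 8.49). That list did not stand apart when matched on transcript length in place of expression.

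Immediate early genes, which neuronal activity induces, were lower as a group. Of 20 genes, 3 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.61 that 16 of 10000 random lists reached or passed. Egr1, a transcription factor, was 2.59-fold lower (2.43 to 2.77), and Arc was the member that was higher. Of 21 clock genes, 1 was higher and 1 lower, with a median of -0.05 that 2539 random lists matched or lay below. Rora was 2.38-fold higher (1.76 to 3.24) and Ciart, listed as Gm129, 2.18-fold lower (1.78 to 2.69).

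**Figure D3:**
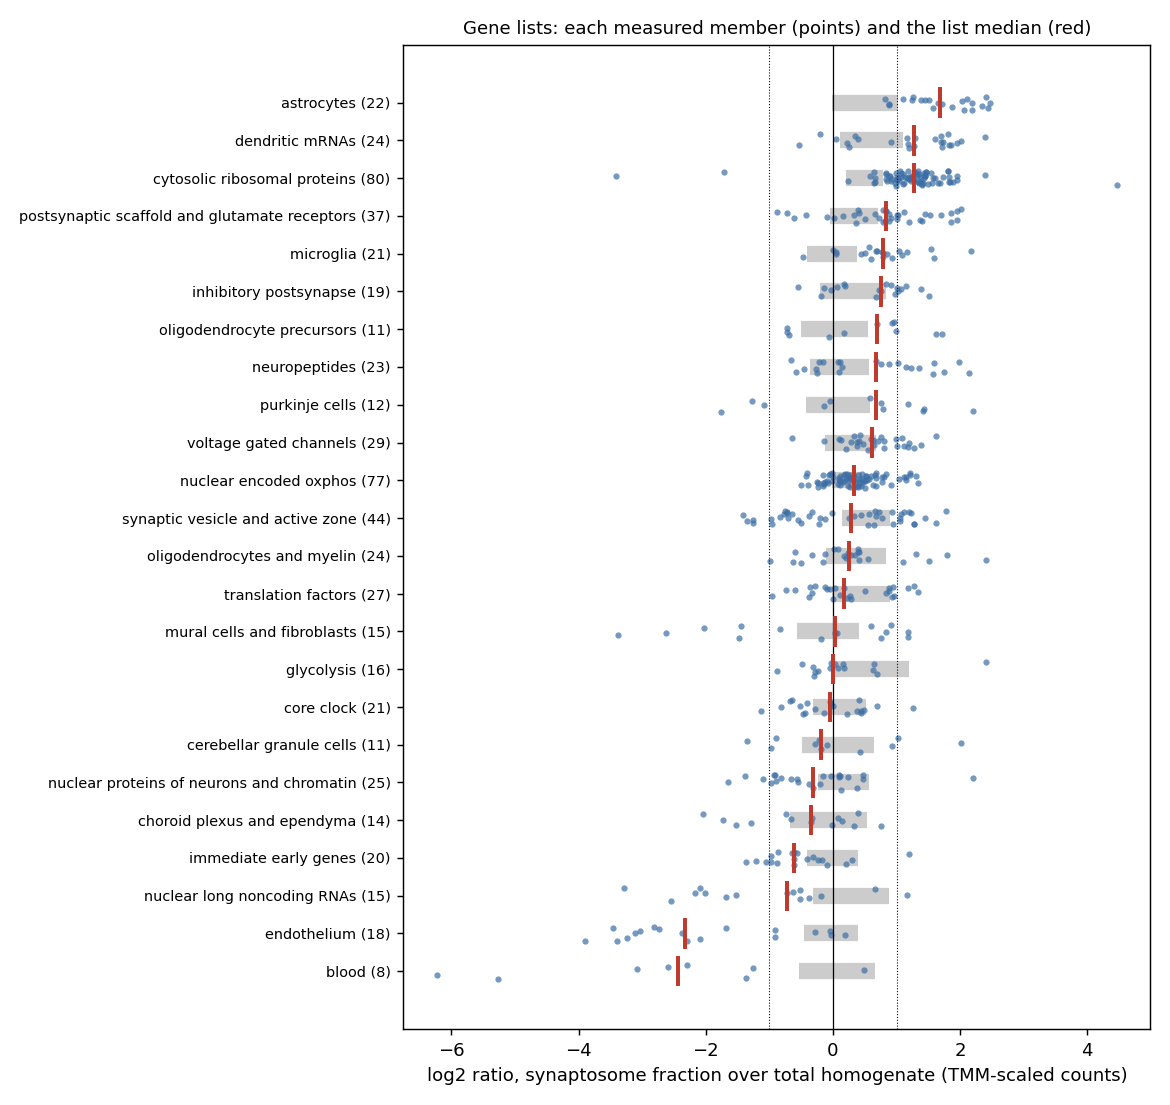
Log2 ratio of the synaptosome fraction over the homogenate (horizontal axis) for each measured member (points) of 24 gene lists (vertical axis, number of members in brackets); red bars are list medians, grey bars the middle 95% of the medians of 10000 random lists matched on expression, dotted lines 2-fold, and a gene with 0 counts in a library is drawn with 3 in its place. The astrocyte list has the highest median, 1.68, and the blood list the lowest, -2.44; under library totals the medians of synaptic vesicle, oxidative phosphorylation, translation factor, oligodendrocyte and mural lists lie below 0.

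Astrocyte mRNAs had the highest median of the 24 lists. All 22 members had ratios above 0 and 19 were at least 2-fold higher, with a median of 1.68 that none of 10000 random lists reached and that was 1.19 under library totals. Gfap, the astrocyte intermediate filament, was 5.54-fold higher (5.34 to 5.74), Sparcl1, a secreted matrix protein, 3.67-fold higher (3.62 to 3.71), and Gja1, the gap junction protein connexin 43, 1.77-fold higher (1.69 to 1.86). Slc1a2 (chromosome 2, 102658683 to 102790784) had 41912 counts in the homogenate and 116335 in the synaptosome fraction.

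Myelin genes were split. Of 24 oligodendrocyte and myelin genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.26 that became -0.24 under library totals, and 3487 random lists lay as low. Mbp was the most abundant gene of the synaptosome fraction, with 1.44% of its counts against 0.382% in the homogenate. Aspa, an oligodendrocyte enzyme, was 1.98-fold lower (1.62 to 2.44). Of 11 genes of oligodendrocyte precursors, 2 were at least 2-fold higher and 0 lower, with a median of 0.69 that 75 random lists reached. Tnr, a matrix protein, was 3.27-fold higher (2.97 to 3.62) and Sox10, a transcription factor of the lineage, 1.65-fold lower (1.46 to 1.87). With the mean in place of the median, 0.44, this list no longer stood apart.

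Microglial mRNAs were higher, with 6 of 21 at least 2-fold higher and 0 lower and a median of 0.78 that none of 10000 random lists reached. Tyrobp, a microglial signalling adaptor, was 4.50-fold higher (3.75 to 5.42), C1qa, a complement component, 2.24-fold higher (1.96 to 2.56), and Csf1r, the receptor for the microglial growth factor, 1.81-fold higher (1.68 to 1.94). Gpr34 was 1.39-fold lower (1.03 to 1.89).

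Endothelial mRNAs were lower by more than any other cell type list except blood. Of 18 genes, 12 were at least 2-fold lower and 0 higher, with a median of -2.33 that none of 10000 random lists matched. Slco1a4, an organic anion transporter of the blood-brain barrier (chromosome 6, 141805440 to 141856171), was 15.0-fold lower (11.1 to 20.7), with 1028 and 44 counts. Bsg and the glucose transporter Slc2a1, which other brain cells also make, had ratios near 1, at 1.15 and 0.982. Of 8 blood genes, 7 were at least 2-fold lower, with a median of -2.44, and none of 10000 random lists lay as low. Hba-a1 was 8.44-fold lower (7.46 to 9.59). Hba-a1 and Hba-a2, near-identical copies, together had a log2 ratio of -3.21.

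Other vessel, ventricle and cerebellar lists stood less far apart. Of 15 mural cell and fibroblast genes, 5 were at least 2-fold lower and 2 higher, with a median of 0.03 that became -0.46 under library totals and that 2900 random lists reached. Kcnj8, a pericyte potassium channel with 65 and 4 counts, was 10.4-fold lower (3.88 to 39.3), and Col3a1, a fibroblast collagen, 2.26-fold higher (1.80 to 2.85). Of 14 choroid plexus and ependymal genes, 4 were at least 2-fold lower and 0 higher, with a median of -0.34 that 2140 random lists reached or passed. Ttr, transthyretin of the choroid plexus, was 2.89-fold lower (2.75 to 3.04), while Enpp2 was 1.31-fold higher, with a log2 ratio of 0.39 that became -0.10 under library totals. Of 11 cerebellar granule cell genes, 2 were higher and 1 lower (median -0.19, with 2238 random lists as low). Their most abundant members, Slc17a7 at 1.91-fold higher and Reln at 4.05-fold higher, are also made in the forebrain. Of 12 Purkinje cell genes, 4 were higher and 3 lower, with a median of 0.67 that 134 random lists reached. Itpr1 was 2.27-fold higher, Car8 4.63-fold higher and Calb1 3.38-fold lower, and all are made outside the cerebellum too. The Purkinje list did not stand apart without the members it shares with other lists (median 0.27), and the Purkinje-specific Pcp2 had 0 counts in both libraries.

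Among the 12 genes with the highest ratios, Ndrg2 (chromosome 14, 51905271 to 51913488) was 6.33-fold higher (6.22 to 6.45), with 14141 and 57341 counts, S100a1, a calcium-binding protein, 7.36-fold higher (6.76 to 8.03), and Acsbg1, an acyl-CoA synthetase, 5.76-fold higher (5.50 to 6.03). Myom3, a sarcomere protein, was 7.60-fold higher, Hipk2, a kinase, 6.90-fold, Metrn, a secreted protein, 6.58-fold, Proca1 6.43-fold, Slc25a34, a mitochondrial carrier, 6.16-fold, and Kcne1l, a potassium channel subunit, 5.96-fold. Olfr287, an olfactory receptor gene, was 6.01-fold higher (4.76 to 7.65), and with its near-identical copy Olfr288 its log2 ratio was 2.54. The top places, Tgoln2 with 0 and 281 counts and Rpl34 at 22.0-fold higher, are uncertain. Tgoln2 was 146-fold higher against a floor of 3 counts, with an interval limit of 118-fold. Summed with the related Tgoln1, Tgoln2 had a log2 ratio of 0.54, and Rpl34 summed with a near-identical pseudogene had one of 1.55.

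Of the 12 genes with the lowest ratios, Slco1a4, Ly6c1, Ly6a and Eltd1 are endothelial genes and Hba-a1, Hba-a2 and Hbb-b2 are globins. Ly6c1 was 11.0-fold lower (7.53 to 16.8), Eltd1 10.5-fold lower and Ly6a 10.5-fold lower. Hbb-b2, with 480 and 8 counts, was 38.4-fold lower (19.3 to 89.5), and 6.56-fold lower when summed with Hbb-b1 and Beta-s. Hba-a2, with 350 and 0 counts, was 74.7-fold lower against a floor of 3 counts, with an interval limit of 60.4-fold, and is uncertain. Its log2 ratio was -3.21 summed with Hba-a1. The authors' deposited signal gave -2.71 for Hba-a2 and -3.93 for Hbb-b2. Neat1, Amy1, an amylase at 8.01-fold lower (6.03 to 10.8), and Cdc7, a replication kinase at 7.58-fold lower (5.22 to 11.4), were also among them. Amd1, with 346 and 0 counts, and Rps27, at 10.7-fold lower, are uncertain: summed with near-identical copies, Amd1 had a log2 ratio of 0.10 and Rps27 one of 1.51, and the authors' deposited signal gave -0.24 for Amd1 and 1.16 for Rps27.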

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

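Matching on GC content, leaving out Rn45s and Gm20594, sums with near-identical copies, lists without shared members, and library totals for the lists and annotation terms added later were chosen after the data were seen. No paired test was possible with 1 library per fraction, and the result comes from no test. Both labels carry the number 1, so the libraries may be a matched pair, which the labels do not state. With 1 library per fraction no library could be left out. The alternatives without mitochondrially encoded genes, and that for their share of counts, were not run, since the files held 0 such rows.

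The 1807 genes at least 2-fold higher became 636 under library totals, 470 with TPM, 3391 at 1.5-fold and 169 at 4-fold. The 1288 lower became 3629, 3005, 2953 and 185, and 578 among genes with at least 10 CPM, where fewer genes entered. Both counts stayed within 1.5 times the main ones under DESeq2 size factors, the authors' signal, no expression filter, no interval and without Rn45s and Gm20594. Library totals moved all ratios down together. Under library totals and under TPM 5 of 24 list medians that were above 0 lay below it: synaptic vesicle (-0.20 and -0.25), oxidative phosphorylation (-0.16 and -0.21), translation factors (-0.32 and -0.36), oligodendrocytes (-0.24 and -0.28) and mural cells (-0.46 and -0.50). The other 19 kept direction under both. No list changed its standing under either, which for library totals was fixed in advance, since all ratios move by the same amount.

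DESeq2 size factors turned only the glycolysis median, from -0.00 to 0.02, and the authors' signal only the same one, to 0.00. As a mean it was 0.14, and matched on length or GC content, at -0.00, it no longer stood apart (percentiles 59.58 and 34.46). Such matching replaced that on expression, so these percentiles do not show whether length, GC content or abundance moved a list. Matching on length or GC content also ended the standing of nuclear proteins of neurons, at -0.32 (4.52 and 4.62). It made that of the inhibitory postsynapse, at 0.75 (99.92 and 99.99), and of voltage-gated channels, at 0.62 (99.77 and 99.94), and GC matching alone made that of oxidative phosphorylation, at 0.33 (99.39). As means, voltage-gated channels (0.64) and synaptic vesicle genes (0.16, percentile 0.4) stood apart, precursors (0.44) and Purkinje genes (0.34) did not, and mural cells (-0.43) and granule cells (0.03) turned. Without the filter, neuropeptides (0.49) and Purkinje genes (0.59) no longer stood apart and mural cells lay at -0.08. At 10 CPM or more, neuropeptides (0.41) did not stand apart and mural cells (0.60) did. Without shared members the Purkinje list (0.27) did not, while 15 other lists kept their standing. Leaving out Rn45s and Gm20594 altered the standing of 0 of 24 lists.

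Of 40 named genes, 31 under library totals and 30 with TPM lay outside their counting intervals, as did 6 under DESeq2 size factors, 7 with the authors' signal, 0 with log CPM and 0 without Rn45s and Gm20594. Of 9 summed with copies, 3 stayed inside. Rps27 turned to 1.16 with the authors' signal and 1.51 with its copy, and Amd1 to 0.10 with its copy. The copies held most of the counts in these sums, and whether reads were split between copies was not tested. Under library totals and DESeq2 size factors every log2 ratio moved by a fixed amount, -0.493 and 0.0269. Genes outside their intervals there are those whose intervals did not reach that far. The cause of the other shifts was not tested. Some named genes rest on few counts, such as Kcnj8 on 65 and 4.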

Other observations

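The gene lists, annotation terms and region markers used here were chosen after the first list results were seen, as were the tests of a lower share of neuronal RNA and all matching on GC content, while the other tests were fixed before the values they measure.

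mRNAs of reticulum and lysosome proteins lay above the typical gene and those of proteasome and cytosolic chaperones below it, mostly by less than 2-fold. Of 24 endoplasmic reticulum residents, 10 were at least 2-fold higher and 0 lower (median log2 ratio 0.83, reached by 30 of 10000 random lists), among them the chaperones Hspa5, at 2.86-fold (2.76 to 2.97), and Calr, at 2.35-fold (2.28 to 2.42). Of 29 lysosomal protein genes, all had ratios above 0, or 22 under library totals, and 6 were at least 2-fold higher (median 0.69, reached by 34 random lists), with Gaa, the acid glucosidase, at 2.88-fold. Of 32 proteasome subunits, 28 had ratios below 0 and 1 was at least 2-fold lower, namely Psmc2 at 2.07-fold (median -0.29, with 45 random lists as low). Of 18 cytosolic chaperones, 17 had ratios below 0 and 0 were at least 2-fold lower (median -0.41, with 7 random lists as low), with Hsp90aa1 at 1.87-fold lower (1.83 to 1.92). By annotation, 762 genes of the extracellular region had a median of 0.43, 859 of the endoplasmic reticulum one of 0.40 and 859 of the Golgi apparatus one of 0.20, and these became -0.06, -0.09 and -0.29 under library totals. Relative to the typical gene, 4213 genes of the nucleus lay at -0.21, 120 of the spliceosomal complex at -0.38 and 131 of the cilium at -0.32. The 335 synapse genes had a median of 0.57, or 0.08 under library totals. The 113 postsynaptic density genes lay at 0.43, 255 dendrite genes at 0.41 and 191 axon genes at 0.46, and these became -0.06, -0.08 and -0.03 under library totals.

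Genes of motors, tubulins and the vacuolar ATPase were examined as well, without a test of one group against another. Of 19 kinesin genes, 8 were at least 2-fold higher and 0 lower, with Kif1c at 5.50-fold (5.23 to 5.79) and Kif1a at 3.03-fold, while Kif3a fell just short of 2-fold lower. The kinesin median of 0.26 became -0.23 under library totals, and 2892 of 10000 random lists lay as low, so the list did not stand apart. Of 18 dynein and dynactin genes, 0 were higher and 1 lower (median -0.36, with 48 random lists as low), with Dync1i2 at 2.10-fold lower (1.96 to 2.26). Of 10 tubulin genes, 1 was higher and 2 were lower (median -0.50, with 24 random lists as low), with Tubb2b at 4.02-fold higher (3.84 to 4.21) and the neuronal Tubb3 at 2.08-fold lower (1.97 to 2.21). Of 14 vacuolar ATPase genes, 2 were higher and 2 lower (median -0.45, with 8 random lists as low), and these last 3 lists stood apart. The accessory membrane proteins Atp6ap1 and Atp6ap2 were the higher ones, at 2.25-fold and 2.33-fold, and the cytosolic subunits Atp6v1d, at 2.12-fold, and Atp6v1g2 the lower ones.

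Astrocyte mRNAs were higher and endothelial mRNAs lower in the same library. A lower share of neuronal RNA alone would put every other cell type above 0, whereas the endothelial median was -2.33 (bootstrap 95% interval over genes -3.07 to -0.91). That median is part of the pattern itself and was known when the test was set, so it adds no separate evidence. GC content is argued against by the astrocyte list's percentile of 100 among lists matched on it. For whole astrocytes in the fraction, 16 astrocyte nuclear-protein mRNAs all had ratios above 0 and 8 were at least 2-fold higher. None of 10000 random lists reached their median of 1.01. Their difference of -0.67 from the astrocyte list (-1.2 to -0.33) met the bound set in advance. The lists differ in abundance, however: random lists matched on expression had medians of -0.06 for the nuclear-protein list and 0.53 for the astrocyte list. The difference, taken without such matching, therefore cannot decide about whole astrocytes. The raised nuclear-protein mRNAs leave a part played by whole astrocytes open, and pinched-off astrocyte processes in the collected layer were not tested.

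Nuclear long noncoding RNAs were lower in the synaptosome fraction. GC content and transcript length are argued against by percentiles of 0.0 and 0.12 for the list among random lists matched on each. Loss of nuclei, which the low-speed spin removed, was tested on 24 splicing-related genes whose transcripts are often held in the nucleus with an unspliced intron: 19 were at least 2-fold lower and 0 higher, with a median of -1.31 and a percentile of 0.0 among lists matched on expression. Examples were Srrm2 at 2.41-fold lower and Sfrs18 at 3.80-fold lower (3.51 to 4.12). The pattern is consistent with loss of nuclei as a hypothesis, and a difference in RNA decay between the fractions stays open and untested.

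mRNAs of secreted and membrane proteins lay above the typical gene by annotation, at 0.43 for the extracellular region and 0.35 for the 2137 genes of the plasma membrane, but at -0.06 and -0.14 under library totals. GC content is argued against by a percentile of 100 for reticulum and lysosome mRNAs among lists matched on it, a test set after their medians were seen. Astrocyte RNA as the whole cause was taken to predict that endoplasmic reticulum residents, which all brain cells use, would not exceed proteasome and chaperone mRNAs. The residents lay 1.16 above proteasome and cytosolic chaperone mRNAs (bootstrap 95% interval 0.93 to 1.43). This cannot decide about astrocyte RNA, since levels in astrocytes were not measured and astrocytes may hold more of the residents. A candidate explanation is endoplasmic reticulum carried into the fraction with its bound mRNAs. As that candidate predicted, reticulum and lysosome mRNAs together lay 1.08 above the cytosolic ones (0.94 to 1.23). Nearly the same contrast was used above for astrocyte RNA, so it does not separate this candidate from others. Synaptic location of these mRNAs, the difference the design names, was not tested apart from reticulum in the fraction.

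The tissue label is whole brain, and markers of its regions were examined in both libraries. Gabra6 of granule cells and Pcp2 of Purkinje cells had 0 counts in each, which in the homogenate allows up to 0.197 CPM, and Cbln3 had 6 and 6 counts. Of 10 pons and medulla markers, 0 reached 1 CPM in the homogenate, and Hoxa3, Hoxa5, Hoxb2, Hoxb4, Hoxb5 and Hoxc4 had 0 counts in both. Of 12 cerebellar markers 6 reached it: Grm4 at 17.6, Gdf10 at 9.07, En2 at 2.24, Barhl1 at 1.64, Barhl2 at 1.32 and Cdh15 at 1.18 CPM. All 10 cortex and hippocampus, 9 striatum and 8 thalamus markers reached it, as did 7 of 8 for the olfactory bulb, 5 of 8 for midbrain and raphe, and 5 of 10 for the hypothalamus. Tbr1 was counted for both cortex and olfactory bulb. Median CPM in the homogenate was 0.0 for pons and medulla, 0.92 for cerebellum and 1.12 for hypothalamus markers, against 49.9 for cortex and hippocampus. Pons and medulla markers were thus nearly absent, and the cerebellar Gabra6 and Pcp2 were not detected, although the label is whole brain.

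Ribosomal RNA-like genes took more of the synaptosome library. Rn45s held 0.0815% of counts in the homogenate (exact 95% interval 0.0801 to 0.083) and 0.243% in the synaptosome fraction (0.241 to 0.246). Gm20594, whose transcript matches the mitochondrial ribosomal RNA gene mt-Rnr2 at 88.4% over 439 of its 449 bases, held 0.0621% and 0.260%.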
